A study of Mus musculus with 24 samples.

How the data were processed

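The series measured RNA in mouse dorsal root ganglia, the clusters of sensory neuron cell bodies and their glia beside the spinal cord, after a crush of the sciatic nerve. Per the labels, C57BL/6 mice aged 12 weeks received camptothecin, an inhibitor of DNA topoisomerase I, at 2 mg/kg into the peritoneum 30 minutes after the crush, or vehicle, and ganglia were taken at 18, 24 or 36 h. The labels hold 6 groups of 4 samples, 24 in all, and no uninjured group. Columns of 19 samples were used, and the other 5 samples were not analysed here. Per the labels' protocols, total RNA was made into cDNA with the Nugen Ovation RNA-Seq V2 kit, sheared by Covaris and sequenced from both ends. The same text also speaks of an immunoprecipitated or flow-through RNA, a wording that does not match whole ganglia.

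The deposited table held 19571 Ensembl transcripts with their symbols, a raw count per sample, a log2-scale variance-stabilised value per sample, and the authors' comparisons of camptothecin with vehicle at each time. Per the submitters' processing notes, CASAVA 1.8.2, limma and the mm10 genome were used. The aligner, the counter, the annotation version and the tool for the variance-stabilised values are not given in the sources used here. The counts were whole numbers, per the file headers and the values. The table held 0 mitochondrial transcripts. Gapdh, a gene with many pseudogenes, reached at most 3.13 counts per M counts (M for mega), so reads with several matching places were apparently lost or split. Transcripts of 1 gene were counted as separate features, so reads shared by isoforms or by near-identical copies such as the globin genes are uncertain. The smallest total over the 19 columns was 75 counts, so transcripts below that level had been removed. The authors' deposited p-values and adjusted p-values equalled those of limma on their log2-scale values with 6 group means, to within 5.94e-13 at 18 h.

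Columns carried a letter, a time and a replicate number. Time and number matched the sample titles, but the letters A and B had no legend. The letter A was taken as vehicle because the deposited log2 fold changes, whose headers name camptothecin against vehicle, equalled the mean of the B columns minus the mean of the A columns for all 19571 transcripts. The largest difference was 8.7e-14 at 18 h against 4.32 with the letters exchanged. The arm of every sample therefore rests on the authors' own named contrasts and not on the column names alone. The labels do not say that the samples came from separate animals, so p-values measure the spread between these samples, which may be technical. No 2 replicates matched within counting noise (chi-square per degree of freedom between 3.31 and 22.8).

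Counts were tested with edgeR 4.0.16 in R 4.3.3. Transcripts were filtered by filterByExpr (min.count 10, min.total.count 15), which left 18606 transcripts of 13677 symbols and removed 965. Libraries were scaled by TMM, and 1 quasi-likelihood fit of 6 group means over the 19 libraries had 13 residual degrees of freedom and a common dispersion of 0.0665. Contrasts were camptothecin against vehicle at each time and averaged over the 3 times, the difference of that effect between times, and 24 h and 36 h against 18 h within each arm. Adjusted p-values are Benjamini-Hochberg values over all tested transcripts, two-sided, with a threshold of 0.05. The standard error (SE) of a log2 fold change was its size divided by the square root of the quasi-likelihood F. Levels are counts per M counts (CPM) of the total over tested transcripts times the TMM factor, with the SD over libraries. The Gapdh value and the ratios of transcripts with few counts used totals without that factor. The 291 transcripts without a symbol held between 0.501% and 0.568% of the counts and stayed in the totals.

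The tests, the gene lists, the rule for naming genes and the first set of alternatives were chosen before the data were examined. That design allowed for either counts or normalised values and assumed 24 samples; with counts of 19 samples, the edgeR test was used on those. The naming rule took up to 8 largest rises and 8 largest falls among passing transcripts whose camptothecin libraries all lay on one side of the vehicle libraries, leaving out unnamed loci, and the 3 smallest p-values in a direction where fewer passed. It added up to 4 members of each list with the smallest p, and always Top1, Atf3, Jun, Sox11, Sprr1a, Gal, Npy, Gap43, Gadd45a, Cdkn1a and Mdm2. Some transcripts taken by the rule are not reported here and are left out of the counts of named transcripts. Time comparisons took 5 rises and 5 falls and the difference between times the 6 smallest p-values. The rule spoke of 4 samples against 4 and of genes; it was applied to 3 or 4 libraries per group and to transcripts. Other members named in the time comparisons and in the descriptions of lists were chosen after their values were seen.

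Of 29 gene lists, 28 had measured members, with the most abundant transcript standing for each symbol. They covered regeneration-associated genes, p53 targets, DNA repair, topoisomerases, immediate early genes, very long genes, sensory ion channels, sensory subtypes, and pan-neuronal genes. Cell type lists were satellite glia, Schwann cell and myelin genes, macrophages, neutrophils, lymphocytes, endothelium, mural cells, fibroblast matrix, erythroid genes, skeletal muscle and adipocytes. The rest were cell cycle, interferon-stimulated genes, inflammatory cytokines, the circadian clock, glucocorticoid response, cholesterol synthesis, endoplasmic reticulum stress and hypoxia targets. The mitochondrially encoded list had 0 measured members. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 28 lists, and again with an estimated correlation. Member counts are given over all transcripts tested and adjusted over the list alone.

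Transcript GC content, exons and positions came from GENCODE M21 on GRCm38, the assembly that mm10 names. Of the deposited identifiers 19148 matched, and 97.9% of tested transcripts (18213) had a GC value. Coordinates are 1-based. A GC correction fitted a spline with 5 degrees of freedom per library to the deviations of log2 CPM and entered it as offsets.

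Total counts ran from 3.62 M to 15 M per library. Scripts were tested on simulated counts with 100 transcripts changed 2-fold and 100 changed 4-fold among 18279, all drawn from those above a minimum mean count. Of these, 51% and 87% were recovered at 18 h with 6 false calls, 62% and 90% at 24 h with 10, 54% and 88% at 36 h with 3, and 83% and 99% for the average with 7. Counts for 18261 unchanged transcripts were also given the GC trends of the real libraries. Then 2, 1, 5 and 419 false calls were made at 18 h, 24 h, 36 h and for the average. With the GC correction there were 0, 0, 0 and 1. With 200 of 18317 transcripts changed and those GC trends, false calls numbered 49, 27, 68 and 579. With the GC correction these numbered 10, 5, 6 and 18. Alternatives were other scaling (DESeq2 size factors, also called RLE), no low-count filter, DESeq2 1.42.0 and limma-voom. Others were a fit of the compared groups alone, the replicate number as a block, and each library left out. Added after the data were seen were limma on the deposited values, the GC correction alone and with the block, and log2 library total as a covariate. Thinning to the smallest total, sums per symbol, and leaving out the libraries numbered 4 were also added then.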

Results

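RNA was measured in dorsal root ganglia of mice at 18, 24 and 36 h after sciatic nerve crush, with camptothecin or vehicle given 30 minutes after the injury. Injured sensory neurons switch on a set of genes tied to axon regrowth, and the design asks how an inhibitor of topoisomerase I alters the RNA of the ganglion over the first 36 h. Vehicle had 3 libraries at each time. Camptothecin had 3 at 18 h, 4 at 24 h and 3 at 36 h. Vehicle libraries held 4.04 ± 0.388 M counts at 18 h, 6.84 ± 1.28 M at 24 h and 4.65 ± 1.03 M at 36 h (mean ± SD, n = 3 each). Camptothecin libraries held 8.02 ± 1.85 M (n = 3), 11.4 ± 2.91 M (n = 4) and 9.85 ± 0.56 M (n = 3) at those times. Every vehicle library was shallower than every camptothecin library of its time, and the arms differed in GC trend as well. The rank correlation across transcripts between a library's deviation in level and GC content ran from -0.312 to 0.056 in vehicle and from -0.08 to 0.319 in camptothecin. Transcripts are not independent replicates, so these values only describe the libraries.

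**Figure D1:**
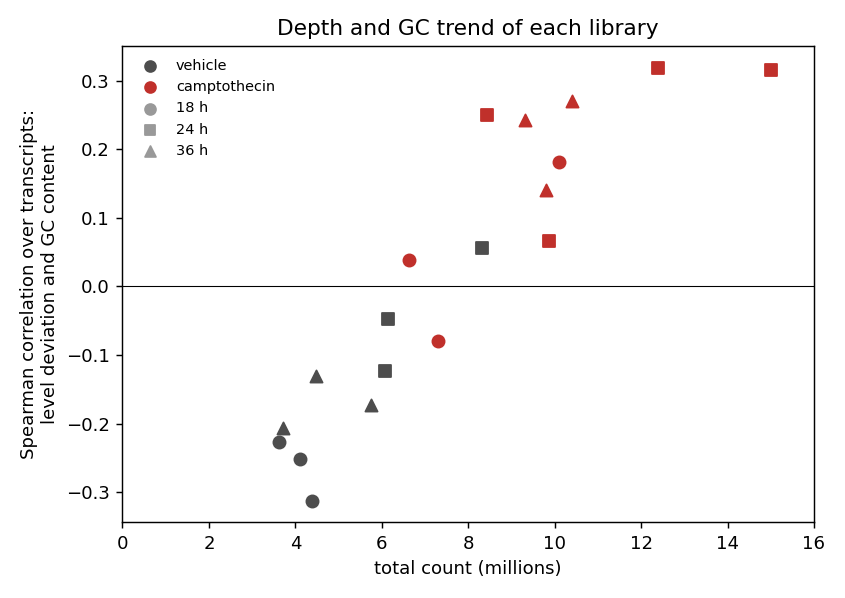
Each point is 1 library, with its total count in M on the horizontal axis and, on the vertical axis, the Spearman correlation across transcripts between its deviation in level and transcript GC content. Colour gives the arm and shape the time; vehicle libraries lie between -0.312 and 0.056 and camptothecin libraries between -0.08 and 0.319.

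At 18 h camptothecin was compared with vehicle to ask how the drug changed the early response. Neuropeptide Y (Npy, ENSMUST00000031843, chromosome 6, 49822710 to 49829507, plus strand, 4 exons) rose from 0.893 ± 0.385 to 5.64 ± 3.40 CPM (SD, n = 3 and 3), a log2 fold change of 2.67 ± 0.47 (SE; adjusted p = 0.0159). Its vehicle libraries held 1.17, 1.06 and 0.452 CPM, a few counts each, and its camptothecin libraries 4.08, 3.31 and 9.54 CPM. The neuropeptide galanin (Gal, ENSMUST00000025842, chromosome 19, 3409932 to 3414447, minus strand, 6 exons) rose from 15 ± 8.67 to 39.9 ± 10.5 CPM (1.42 ± 0.29, adjusted p = 0.0281). Serpinb1a, a serine protease inhibitor (chromosome 13, 32842092 to 32851185), rose from 5.76 ± 1.45 to 14.4 ± 1.36 CPM (1.31 ± 0.21, adjusted p = 0.0129), as did the cholecystokinin receptor Cckbr (1.30 ± 0.32). Kcna4, a voltage-gated potassium channel (chromosome 2, 107290639 to 107298502), fell from 194 ± 30.1 to 63.8 ± 9.73 CPM (-1.60 ± 0.24, adjusted p = 0.0127). Rbm25, an RNA-binding splicing factor (a transcript of 1 exon), fell from 18.9 ± 1.07 to 4.77 ± 1.36 CPM (-1.99 ± 0.35, adjusted p = 0.0159).

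Other large rises at 18 h were Fuz (1.66 ± 0.38), the potassium channel subunit Kcnab2 (1.63 ± 0.39), Ccdc92 (1.17 ± 0.21) and Sap30bp (1.12 ± 0.28). Other large falls were Asxl2 (-2.33 ± 0.51), Tpd52l2 (-2.25 ± 0.53), the ubiquitin ligase Ubr3 (-2.17 ± 0.52), Pstk (-1.99 ± 0.46) and Ap1s3 (-1.98 ± 0.51), with adjusted p between 0.0323 and 0.0495. Of the regeneration-associated list 5 of 27 members rose and 0 fell (8 and 0 adjusted over the list alone), with Npy, Gal, Cckbr, the receptor Gpr151 (1.08 ± 0.21) and the injury-induced transcription factor Atf3 (0.59 ± 0.13, 344 ± 59.4 to 519 ± 24.7 CPM). The list's median log2 fold change was 0.35 (camera adjusted p = 1.68e-08; adjusted p = 0.362 with an estimated correlation), and it was the sole list of 28 to pass. With the replicate number as a block the very long and erythroid lists also passed, both lower (camera adjusted p = 0.0289 each), and with the GC correction the erythroid list (camera adjusted p = 0.0191). With an estimated correlation the adjusted p was 0.758 for both lists, and 0.719 for the erythroid list with the GC correction. Sprr1a, an injury-induced gene, had 1.35 ± 0.38 (adjusted p = 0.069), Sox11 0.31 ± 0.14, Gap43 0.30 ± 0.13 and Jun 0.00 ± 0.10, none of which passed. Among neuronal genes the transcription factor Isl1 fell (-0.93 ± 0.21), while the cytoskeletal genes Tubb3 (0.45 ± 0.11) and Nefh (0.47 ± 0.11) rose. Of the p53 targets 1 of 21 passed, Zmat3 (-0.72 ± 0.18), with 0 higher and 2 lower adjusted over the list alone, and Cdkn1a (0.21 ± 0.20) and Mdm2 (-1.11 ± 0.46) did not pass. DNA repair genes had 0 of 24 passing by edgeR. Top1, the target of the drug (chromosome 2, 160645888 to 160722764), had -0.37 ± 0.16 (adjusted p = 0.256).

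In all, edgeR called 294 transcripts of 287 genes at 18 h, 59 higher and 235 lower (79.9% lower); DESeq2 called 961, 372 higher and 589 lower (61.3% lower). Called falls had a median transcript GC content of 41.4% and rises of 54.2%, against 48.2% over all, and 22 transcripts were called with the GC correction. With the log2 library total as a covariate edgeR called 0 (794 at an unadjusted p under 0.05). That total separated the arms at each time, so a count of 0 with it cannot tell depth from the drug. The count was 12, 46 and 286 without vehicle library 1, 3 or 4, and 5, 1 and 19 without camptothecin library 2, 3 or 4; without vehicle library 3 the calls were 38 higher and 8 lower. Of the 25 named transcripts that passed, 1, 8 and 12 stayed under 0.05 without those vehicle libraries and 2, 1 and 4 without those camptothecin libraries. All 25 kept their direction in every one of these fits. That says little, since they were chosen for passing in the full fit, whose other libraries these fits keep.

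**Figure D2:**
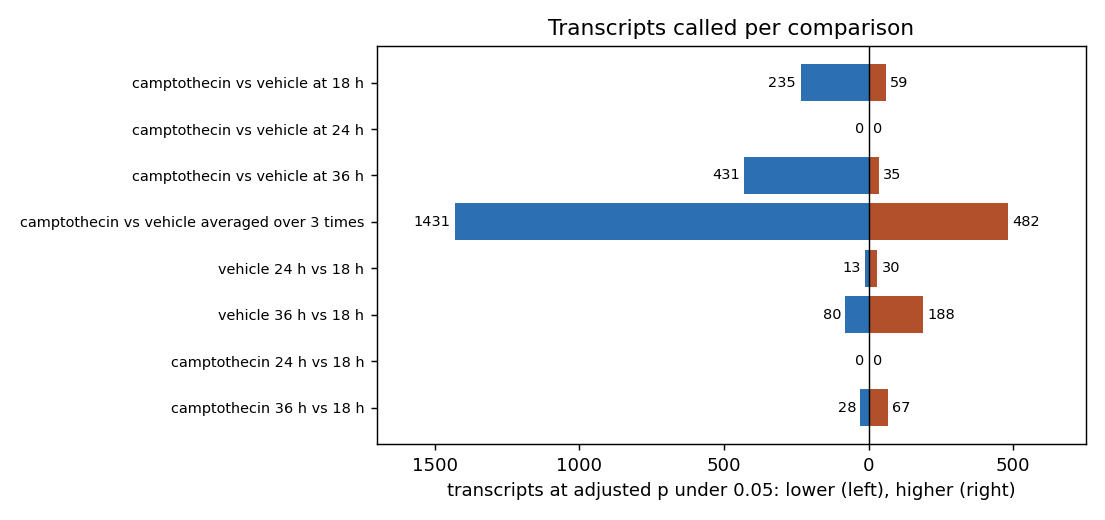
Bars give the number of transcripts called at an adjusted p under 0.05 by edgeR in each comparison, lower to the left and higher to the right of 0. Falls outnumber rises for camptothecin against vehicle at 18 h (235 and 59) and at 36 h (431 and 35), and no transcript was called at 24 h.

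At 24 h no single transcript passed by edgeR with all libraries. The smallest p-values belonged to the metalloprotease Adam9 (-1.56 ± 0.30), Fam13c (-1.69 ± 0.32) and Tcaf1 (-0.89 ± 0.18) among lower values. Among higher values they belonged to the transcription factor subunit Nfyb (2.02 ± 0.45), Gtpbp1 (0.98 ± 0.22) and Eri3. The adjusted p was 0.256 for Eri3 and 0.216 for the others. Eri3 rested on 2 counts over the vehicle libraries and 84 over the camptothecin libraries, a ratio of 18.8 in CPM (95% counting interval 5.06 to 158). Injury genes had values near those of vehicle, with 0.15 ± 0.30 for Npy, 0.25 ± 0.23 for Gal, 0.14 ± 0.32 for Sprr1a and 0.23 ± 0.12 for Atf3. The very long genes were lower as a list (median -0.35, camera adjusted p = 2.04e-05; adjusted p = 0.278 with an estimated correlation), with 0 of 21 members passing and 2 lower adjusted over the list alone; Auts2 had -0.90 ± 0.28. The erythroid list was lower too (median -1.10, camera adjusted p = 0.0215; adjusted p = 0.994 with an estimated correlation), with 0 of 6 members passing and 1 lower adjusted over the list alone. Both lists moved beside a gap in library depth and GC trend between the arms. Both passed camera with the GC correction (adjusted p = 9.36e-05 and 0.00257), but the erythroid list did not without the libraries numbered 4 (adjusted p = 0.18). In that fit 1 list passed camera as higher and 1 as lower. The count of 0 came from edgeR, with 1485 at an unadjusted p under 0.05 and a smallest adjusted p of 0.216. DESeq2 called 124 (9 higher, 115 lower), and limma-voom and limma on the deposited values called 0, as did the authors' deposited table. Leaving out camptothecin library 4 of 24 h gave 1 call, and leaving out any other single library of 24 h gave 0. Without all 4 libraries numbered 4, edgeR called 165, 5 higher and 160 lower.

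Among named transcripts that passed at 36 h, the largest rise was in Zbtb16, a zinc finger repressor known to respond to glucocorticoids. The transcript was ENSMUST00000093852 (chromosome 9, 48654297 to 48835945, minus strand, 7 exons). It rose from 6.35 ± 0.82 to 31.1 ± 1.53 CPM (SD, n = 3 and 3; 2.28 ± 0.36, adjusted p = 0.00469). The metallothionein Mt2 rose from 33.8 ± 9.78 to 99.0 ± 26.1 CPM (1.57 ± 0.33, adjusted p = 0.0142). Red cell genes fell, with Rhag at -4.26 ± 1.03, the anion exchanger Slc4a1 at -3.47 ± 0.92 and the beta globin Hbb-bt at -3.36 ± 0.68, all from group means under 30 CPM in vehicle (Slc4a1 8.54 to 44.7 CPM over its libraries). Top1 fell from 219 ± 50.1 to 136 ± 1.04 CPM (-0.68 ± 0.16, adjusted p = 0.0204) and the stress gene Gadd45a from 752 ± 231 to 374 ± 21.7 CPM (-1.0 ± 0.23, adjusted p = 0.0202).

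Other large rises at 36 h were the angiotensin-converting enzyme Ace (1.99 ± 0.51), Chadl (1.84 ± 0.44), Tspan11 (1.48 ± 0.40), Hif3a (1.44 ± 0.33), Hoxb3 (1.37 ± 0.34) and Zfp940 (1.25 ± 0.34). Other large falls were R3hcc1l (-3.57 ± 0.88), the kainate receptor subunit Grik1 (-3.55 ± 0.80), the axon guidance gene Slit2 (-3.54 ± 0.86), Phldb2 (-3.41 ± 0.78) and the exocyst subunit Exoc5 (-3.36 ± 0.82). Of the glucocorticoid-response list 3 of 9 members rose and 0 fell (4 and 0 adjusted over the list alone), namely Zbtb16, Mt2 and Mt1 (1.06 ± 0.28), and its median was 0.86 (camera adjusted p = 0.000101; adjusted p = 0.113 with an estimated correlation). Fkbp5, a further glucocorticoid-induced gene, had 3.21 ± 1.22 (adjusted p = 0.188). Of the erythroid list 3 of 6 fell (5 adjusted over the list alone), with a median of -2.84 (camera adjusted p = 4.88e-06; adjusted p = 0.129 with an estimated correlation). Of the very long genes 4 of 21 fell (6 adjusted over the list alone), among them Csmd1 (-1.73 ± 0.35), Nrxn3 (-1.29 ± 0.29) and Auts2 (-1.29 ± 0.30), with a median of -0.50 (camera adjusted p = 4.88e-06; adjusted p = 0.113 with an estimated correlation).

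Among cell type lists at 36 h, Schwann cell and myelin genes had a median of 0.52 (camera adjusted p = 0.00802; adjusted p = 0.783 with an estimated correlation), with 1 of 11 higher (4 higher and 1 lower adjusted over the list alone). The member that passed was the myelin gene Pmp22 (0.76 ± 0.17, 78.0 to 131 CPM). Without the libraries numbered 4 its camera adjusted p was 0.209, and with the replicate number as a block 0.311. Fibroblast matrix genes had a median of 0.33 (camera adjusted p = 0.00748; adjusted p = 0.71 with an estimated correlation), with 1 of 10 higher, the proteoglycan Dcn (0.88 ± 0.18, 54.3 to 99.7 CPM), and 1 adjusted over the list alone. Their camera adjusted p was 0.209 without the libraries numbered 4 and 0.162 with the block. The regeneration-associated list did not pass (median -0.09, camera adjusted p = 0.216), with 0 members higher and 3 of 27 lower (4 adjusted over the list alone): Gadd45a, Flrt3 (-0.96 ± 0.24) and Mmp16 (-0.99 ± 0.26). Npy (0.14 ± 0.30), Gal (0.29 ± 0.24), Sprr1a (-0.12 ± 0.34), Atf3 (-0.08 ± 0.13), Jun (-0.21 ± 0.10), Sox11 (-0.19 ± 0.14) and Gap43 (-0.02 ± 0.13) did not pass. Of the p53 targets Plk2 rose (0.66 ± 0.14) and Zmat3 fell (-0.89 ± 0.17), 1 and 1 of 21 (1 and 2 adjusted over the list alone), with Cdkn1a at 0.03 ± 0.20 and Mdm2 at -0.70 ± 0.47. Kcna4 (-1.38 ± 0.24), Isl1 (-0.98 ± 0.21) and the chemokine receptor Ccr2 (-2.11 ± 0.49) also fell.

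edgeR called 466 transcripts of 449 genes at 36 h, 35 higher and 431 lower. Called falls had a median GC content of 41.4% and lay in genes with a median span of 43.4 kb against 27.1 kb over all, and with the GC correction 130 transcripts were called. With the log2 library total as a covariate edgeR called 0 (940 at an unadjusted p under 0.05). The count was 73, 1 and 1015 without vehicle library 2, 3 or 4 and 8, 258 and 199 without camptothecin library 1, 2 or 3. Of the 31 named transcripts that passed, 5, 0 and 28 stayed under 0.05 without those vehicle libraries and 1, 15 and 8 without those camptothecin libraries. All 31 kept their direction in these fits, which again says little for transcripts chosen for passing in the full fit. Without vehicle library 3, Zbtb16 had an adjusted p of 0.0564.

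The falls at 18 h and at 36 h, from comparisons that share no library, had 152 transcripts in common, against 5.44 for independent lists, and the rises had 0 in common, against 0.111. Both comparisons share the gap in depth and GC trend between the arms, so independence is no measure of a lack of drug effect. With the GC correction 59 of the 152 stayed called at 36 h. Of all 235 falls of 18 h, 18 stayed called lower with it, so at most 18 of the 152 stayed called at both times. At 24 h, which shares no library with either, 231 of the 235 falls of 18 h and 426 of the 431 falls of 36 h were also lower (115 and 211 expected from the share of all transcripts lower). Of the rises, 52 of the 59 rises of 18 h and 28 of the 35 rises of 36 h were higher at 24 h (30.1 and 17.8 expected).

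**Figure D3:**
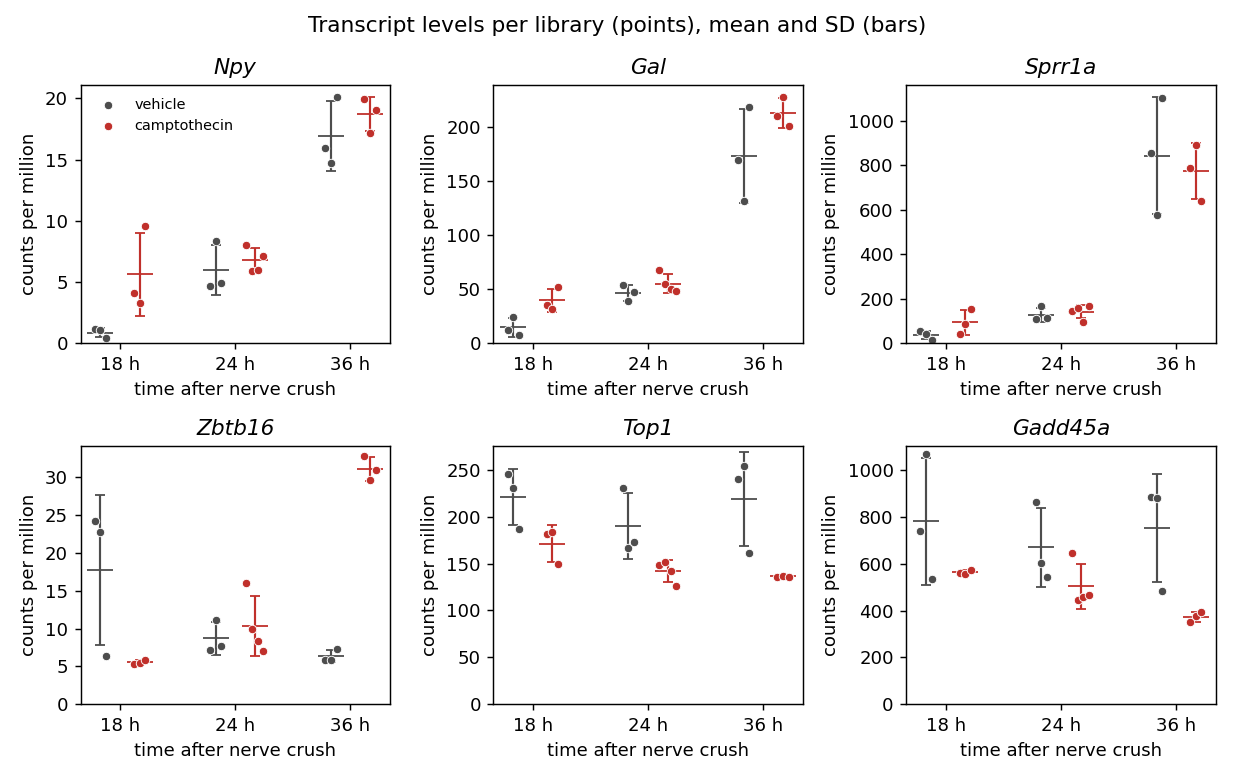
CPM of 6 transcripts in each library (points), with the group mean and SD (bars), for vehicle and camptothecin at 18, 24 and 36 h after nerve crush. Npy is higher under camptothecin at 18 h (5.64 against 0.893 CPM) and Zbtb16 at 36 h (31.1 against 6.35 CPM).

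The mean camptothecin effect over the 3 times was tested too, although such an average can rest on 1 time. The potassium channel Kcna4 (-1.22 ± 0.13, adjusted p = 2.23e-05) and the neuronal transcription factor Isl1 (-0.87 ± 0.12, adjusted p = 5.69e-05) fell. Top1 fell by 0.49 on the log2 scale (SE 0.09, adjusted p = 0.000743) and Top2b, the topoisomerase II of neurons, by 0.36 (SE 0.07), 2 lower and 0 higher of 5 topoisomerase genes (2 and 1 adjusted over the list alone). The DNA ligase Lig4 (-1.16 ± 0.21), the p53 target Zmat3 (-0.57 ± 0.10) and Gadd45a (-0.63 ± 0.13) fell, while Gal (0.65 ± 0.15), Npy (0.99 ± 0.22) and the AP-1 gene Fosl2 (0.41 ± 0.07) rose. The averages of Gal and Npy rested on 18 h, with log2 fold changes of at most 0.29 at 24 h and 36 h. Atf3 rose by less (0.25 ± 0.07, adjusted p = 0.0317). Its adjusted p lay between 0.054 and 0.0753 without vehicle library 4 of 18 h, 1 or 3 of 24 h or 3 of 36 h, or camptothecin library 2 or 3 of 18 h or 1 or 2 of 36 h. Sprr1a (0.46 ± 0.20), Jun (-0.10 ± 0.06), Sox11 (0.03 ± 0.08), Gap43 (0.14 ± 0.07), Cdkn1a (0.08 ± 0.11) and Mdm2 (-0.69 ± 0.26) did not pass.

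For this average 7 of 21 very long genes fell (8 adjusted over the list alone), Csmd1 by 1.33 and Auts2 by 1.13 on the log2 scale, with a median of -0.25 (camera adjusted p = 1.34e-05; adjusted p = 0.23 with an estimated correlation). Of the erythroid genes 5 of 6 fell (5 adjusted over the list alone), with a median of -1.56 (camera adjusted p = 6.01e-05; adjusted p = 0.369 with an estimated correlation). No other list passed camera. The counts higher and lower were 6 and 2 of 27 regeneration-associated genes (6 and 2 adjusted over the list alone), 0 and 3 of 21 p53 targets (1 and 4) and 0 and 1 of 24 DNA repair genes (0 and 1). They were 1 and 0 of 15 immediate early genes (1 and 0) and 0 and 3 of 21 sensory ion channels (0 and 3). Sensory subtype genes had 1 and 0 of 15 (1 and 0) and pan-neuronal genes 3 and 2 of 15 (3 and 2). For glia and immune cells they were 0 and 1 of 8 satellite glia genes (1 and 1 adjusted over the list alone), 2 and 1 of 11 Schwann cell genes (2 and 2) and 0 and 2 of 12 macrophage genes (0 and 2). For processes they were 0 and 2 of 12 cell cycle genes (0 and 2 adjusted over the list alone), 2 and 1 of 15 clock genes (2 and 1) and 2 and 0 of 9 glucocorticoid-response genes (2 and 0). Cholesterol synthesis genes had 1 and 3 of 16 (3 and 4), endoplasmic reticulum stress genes 0 and 1 of 11 (0 and 1) and hypoxia targets 2 and 1 of 14 (2 and 2). By edgeR 0 members passed, over all transcripts or adjusted over the list alone, of 9 neutrophil, 5 lymphocyte, 5 endothelial, 8 mural, 10 fibroblast, 4 skeletal muscle, 4 adipocyte, 17 interferon-stimulated and 8 inflammatory cytokine genes.

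In the average 1913 transcripts of 1778 genes were called, 482 higher and 1431 lower. The count was 950 with the GC correction, and with the log2 library total as a covariate edgeR called 0 (840 at an unadjusted p under 0.05). With the GC correction 24 of 44 named transcripts stayed under 0.05 in the average, 13 of 31 at 36 h and 5 of 25 at 18 h. In the average Top1 then had -0.29 (adjusted p = 0.0641) and Atf3 0.10 (adjusted p = 0.509).

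**Figure D4:**
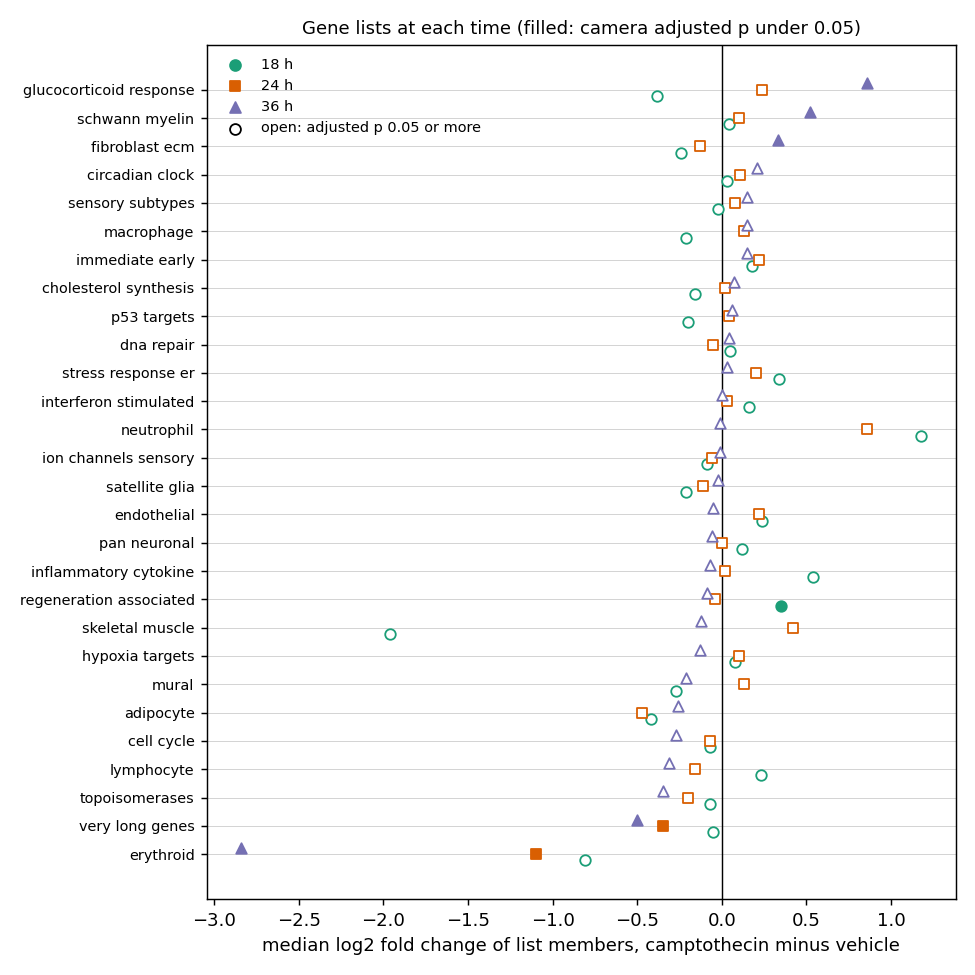
Each marker is the median log2 fold change, camptothecin minus vehicle, of the members of 1 gene list at 18 h (circles), 24 h (squares) or 36 h (triangles), filled where the camera adjusted p is under 0.05. Erythroid genes reach -2.84 and glucocorticoid-response genes 0.86 at 36 h, and regeneration-associated genes 0.35 at 18 h.

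Whether the camptothecin effect differed between the times was tested by an interaction. Zbtb16 was the sole transcript to pass (adjusted p = 0.0144). At 18 h it was lower under camptothecin (-1.66 ± 0.36, 5.29 to 5.80 CPM against 24, 22.8 and 6.33 CPM in the vehicle libraries) and at 36 h higher (29.7 to 32.8 against 5.86 to 7.29 CPM). The next smallest adjusted p-values were 0.103 for the metalloreductase Steap4, 0.448 for Ccdc92 and 0.635 for Shh, Hsp25-ps1 and Serpinb1a. edgeR gave 690 transcripts at an unadjusted p under 0.05; DESeq2 called 12, limma-voom 0 and limma on the deposited values 1. With the replicate number as a block edgeR called 0 (970 at an unadjusted p under 0.05). The count was 0 without vehicle library 1 or 3 of 18 h, vehicle library 2 or 3 of 36 h, camptothecin library 2 or 3 of 18 h, or camptothecin library 1 or 3 of 36 h. It was 2 without camptothecin library 4 of 18 h or of 24 h.

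Within vehicle, 24 h was compared with 18 h after the injury. In this and the other comparisons between times, time of day may differ as well as time after injury. Clock times are not given, so these 2 cannot be told apart. Npy rose by 2.79 ± 0.47, Cckbr by 2.13 ± 0.32, Gal by 1.65 ± 0.29, Gpr151 by 1.70 ± 0.21, Sprr1a by 1.8 ± 0.38 and the growth factor Fgf3 by 2.58 ± 0.47 on the log2 scale. The vehicle libraries of 18 h are the baseline here, at 36 h in vehicle and for camptothecin at 18 h. Like changes in these comparisons, such as those of Npy, Gal, Kcna4 and Rbm25, are therefore not separate evidence. The stress peptide Crh (adjusted p = 0.0356) had 2 counts over the 18 h libraries and 54 over the 24 h libraries, a ratio of 15.9 in CPM (95% counting interval 4.20 to 135). Falls were Plaa (-2.45 ± 0.49), the splicing genes Srsf11 (-1.78 ± 0.35) and Rbm25 (-1.63 ± 0.34) and Kcna4 (-1.18 ± 0.24). Of the regeneration-associated list 5 of 27 rose and 0 fell (13 and 0 adjusted over the list alone; median 0.63, camera adjusted p = 1.30e-16; adjusted p = 0.0392 with an estimated correlation). Cholesterol synthesis genes were lower (median -0.31, camera adjusted p = 6.70e-05; adjusted p = 0.716 with an estimated correlation), with 1 of 16 passing, the sterol sensor Insig1 (-0.56), and 3 lower adjusted over the list alone. edgeR called 43 transcripts, 30 higher and 13 lower. Called rises had a median GC content of 53.3% and falls of 44.4%, against 48.2% over all. Libraries of 18 h were all shallower than those of 24 h (3.62 M to 4.38 M against 6.08 M to 8.32 M). Their GC trend was lower as well (-0.312 to -0.226 against -0.123 to 0.056), so time and these library properties cannot be told apart here. The direction turned with the replicate number as a block (38 higher, 62 lower), in a fit of the 2 groups alone (28 and 67) and without the libraries numbered 4 (40 and 111). With the GC correction 22 were called, and with the log2 library total as a covariate edgeR called 0 (1063 at an unadjusted p under 0.05). Without vehicle library 1, 3 or 4 of 18 h the count was 14, 76 and 5, and 3, 5 and 1 of the 9 named transcripts passed. Without vehicle library 1, 2 or 3 of 24 h it was 11, 7 and 7, and 2, 1 and 2 passed; Cckbr passed in each of these fits.

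From 18 h to 36 h in vehicle, Sprr1a rose from 37.6 ± 18.5 to 843 ± 263 CPM (SD, n = 3 and 3; 4.50 ± 0.41, adjusted p = 1.27e-06). Npy rose from 0.893 ± 0.385 to 16.9 ± 2.83 CPM (4.27 ± 0.45, adjusted p = 8.03e-06) and Gal from 15 ± 8.67 to 174 ± 43.9 CPM (3.55 ± 0.29). The growth cone gene Gap43 (1.17 ± 0.14), Sox11 (0.78), Atf3 (0.54) and Cdkn1a (0.95) rose as well. The largest ratios rested on 1 or 2 counts at 18 h: 69.5 in CPM for the lipase Lipn (95% counting interval 12.1 to 2780), 43.9 for Sox5os3 (11.8 to 367) and 24 for Crh (6.43 to 206). Falls were the peptide Sst (-2.60 ± 0.51), Marveld3 (-2.20 ± 0.38), the growth factor Areg (-1.95 ± 0.45), Naip1 (-1.73 ± 0.40) and the phosphatase Acpp (-1.59 ± 0.26). Of the regeneration-associated list 11 of 27 rose and 0 fell (16 and 0 adjusted over the list alone; median 0.78, camera adjusted p = 3.15e-34; adjusted p = 0.00136 with an estimated correlation). Sensory ion channels were lower (median -0.42, camera adjusted p = 2.83e-05; adjusted p = 0.326 with an estimated correlation), with 4 of 21 falling (8 adjusted over the list alone), the sodium channels Scn11a (-0.87), Scn1a (-0.92) and Scn10a (-0.58) and the irritant receptor Trpa1 (-0.62). Sensory subtype genes were lower (median -0.41, camera adjusted p = 0.000686; adjusted p = 0.326 with an estimated correlation), with 1 of 15 rising and 3 falling (1 and 6 adjusted over the list alone), including Mrgprd (-1.07) and Calcb (-0.94). Cell cycle genes (median 0.68, camera adjusted p = 0.0106; 2 of 12 higher adjusted over the list alone) and macrophage genes (median 0.68, camera adjusted p = 0.0161; 0 of 12 adjusted over the list alone) were higher, with adjusted p of 0.326 and 0.496 with an estimated correlation. Cholesterol synthesis genes were lower (median -0.20, camera adjusted p = 9.33e-05; 1 of 16 lower adjusted over the list alone; adjusted p = 0.326 with an estimated correlation).

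edgeR called 268 transcripts in that comparison, 188 higher and 80 lower. The count was 151 without vehicle library 4 of 18 h and 161 without vehicle library 2 of 36 h. It was 99 without the libraries numbered 4 (82 higher, 17 lower) and 77 in a fit of the 2 groups alone (65 and 12), with 5 and 6 of the 10 named transcripts passing. Of the 10 named transcripts 8, 8, 8 and 7 passed without vehicle library 3 or 4 of 18 h or vehicle library 2 or 4 of 36 h. Areg and Naip1 lost their calls in all of these and Sst without library 4 of 36 h (adjusted p = 0.0533).

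Within camptothecin, no transcript passed at 24 h against 18 h. The smallest p-values among higher values were those of Cckbr (1.15), Ccl9 (1.74) and Arhgef5 (1.77). Among lower values they were those of BC023105 (-1.95), Lgmn (-0.89) and Col25a1 (-1.15), all with an adjusted p of 0.962. Regeneration-associated, macrophage, mural, fibroblast, skeletal muscle and glucocorticoid-response genes were higher as lists by camera, and very long, ion channel, interferon-stimulated and cholesterol genes lower. These 10 lists had camera adjusted p between 0.000558 and 0.024, and adjusted p between 0.401 and 0.434 with an estimated correlation. No member of those lists passed over all transcripts. Adjusted over the list alone 2 regeneration-associated genes were higher and 1 interferon-stimulated gene was lower. The 0 calls were by edgeR, with 940 at an unadjusted p under 0.05. DESeq2 called 1, and limma-voom and limma on the deposited values 0. Without camptothecin library 4 of 18 h or of 24 h the counts were 1 and 2.

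From 18 h to 36 h under camptothecin, Sprr1a rose from 95 ± 55.6 to 774 ± 126 CPM (SD, n = 3 and 3; 3.02 ± 0.37, adjusted p = 0.000182). Gal rose by 2.42 ± 0.25, Zbtb16 by 2.49 ± 0.35, Lipn by 3.93 ± 0.78 and the annexin Anxa10 by 3.45 ± 0.76 on the log2 scale. Areg (-3.44 ± 0.39), the muscle gene Abra (-3.41 ± 0.56), Kprp (-3.48 ± 0.76), Zfp532 (-2.94 ± 0.67) and Zfp142 (-1.33 ± 0.27) fell. Of the regeneration-associated list 7 of 27 rose and 0 fell (7 and 2 adjusted over the list alone; camera adjusted p = 1.66e-06; adjusted p = 0.108 with an estimated correlation). Of fibroblast matrix genes 2 of 10 rose (7 adjusted over the list alone; median 0.71, camera adjusted p = 6.62e-08) and of macrophage genes 2 of 12 rose (4 adjusted over the list alone; median 0.86, camera adjusted p = 2.01e-06), each with an adjusted p of 0.108 with an estimated correlation. Glucocorticoid-response, cell cycle, Schwann cell and skeletal muscle genes were also higher, and ion channel, very long, pan-neuronal, cholesterol and endoplasmic reticulum stress genes lower, by camera. With an estimated correlation the adjusted p of these 12 lists lay between 0.108 and 0.6. edgeR called 95 transcripts, 67 higher and 28 lower. With the replicate number as a block 62 were higher and 61 lower, and without the libraries numbered 4 98 were higher and 112 lower. The count was 36 and 42 without camptothecin library 2 or 3 of 18 h and 41 without library 1 of 36 h. Without camptothecin library 2, 3 or 4 of 18 h 5, 5 and 8 of the 10 named transcripts passed, and without library 1, 2 or 3 of 36 h 5, 6 and 8; Sprr1a, Gal, Zbtb16, Areg and Abra passed in each.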

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

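The tests of GC content as the whole cause, of a property shared with the vehicle time difference, of blood content and both tests of the libraries numbered 4 were chosen only after the results were seen. Tests with the GC correction or thinning were added after the data were seen, with their bounds set before the values they measure were known. The counts over other splits were chosen before.

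At 36 h 431 transcripts fell under camptothecin and 35 rose, and the falls had a median GC content of 41.4% against 48.2% over all transcripts and a median log2 fold change of -1.12 (median SE 0.24, quartiles -1.48 and -0.85). With the GC correction the median was still -0.88 (median SE 0.24, quartiles -1.30 and -0.53, with 429 of 431 negative). These transcripts were chosen for falling in the same libraries, so a median below 0 was partly set by that choice. The value therefore does not decide whether GC bias is the whole cause. After thinning every library to the same total, 99.8% of the median fold remained. Thinning lowers every transcript of a library by the same expected factor, so the fold had to stay near its size. That test cannot decide whether depth plays a part, which stays open. GC bias as the whole or a part of the cause stays open. With the correction 26.2% of the falls (113) stayed called, which met the bound set beforehand for a GC cause. Yet 78.2% of the median fold was kept, and a condition on the fold was added after the values were seen. The median SE was unchanged, and whether smaller folds or the adjustment over all transcripts ended the calls was not separated. Also open is an effect on long genes, which differed under camptothecin with the correction by -0.044 on the log2 scale (genes over 100 kb against the rest, two-sided exact permutation p = 0.00236 over 14000 relabellings within times) and by -0.087 without it (p = 0.000143), so part of the difference went with GC content, but library depth follows the arm, a limit weighed after that value was seen. The transcripts that fell at 36 h differed from all by a median of -0.52 between 24 h and 18 h in vehicle. Of 20 signed splits of those vehicle libraries 1 other gave a lower value. A library property and camptothecin thus cannot be told apart for these transcripts.

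The erythroid list was lower at 36 h with a median of -2.84 and 3 of 6 members passing (5 of 6 in the average over times), but did not pass with an estimated correlation (adjusted p = 0.129, and 0.369 in the average). GC bias as the cause was argued against by a median of -2.77 with the GC correction. Less blood as the whole cause was argued against by the neutrophil list, also of blood, with a median of -0.01 (median absolute deviation 0.18), 9 members between -0.68 and 0.61 (SE 0.74 to 1.19) and a difference of 0.20 ± 0.54 (SE) between library medians, by a bound set after these values were seen; neutrophils within the tissue were not told apart from those of blood. Reads shared between globin copies were not separated, but Slc4a1, which is not a globin, fell too. A drug effect on red cell precursors stays open and untested.

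The 4 libraries numbered 4 held 3.42% to 4.84% of their counts in the nuclear RNA Malat1, and all others at most 2.51%. Lower depth as the cause was argued against, since 2 of the 4 were the deepest of their group and 0 the shallowest, and within groups Malat1 share and log2 total had Pearson r = 0.13 (permutation p = 0.691, adjusted 0.691 over 3 relations, n = 19), Spearman rho = 0.05 (permutation p = 0.866), and r = 0.40 without the 2 libraries farthest from the median depth, while Malat1 share and GC trend had r = -0.60 (permutation p = 0.0279, adjusted 0.0837) and GC trend and log2 total r = 0.55 (permutation p = 0.0813, adjusted 0.122; rho = 0.58, permutation p = 0.0424, adjusted 0.0754), so a tie of Malat1 to the GC trend stays open. The deviations of these libraries from their group means correlated with each other in all 6 pairs, with r between 0.23 and 0.45, but camptothecin library 2 of 36 h (Malat1 2.38%) and vehicle library 2 of 24 h (2.51%) also correlated with all 4 of them (0.18 to 0.39 and 0.10 to 0.20), so a shared condition may be the source but is not particular to the number 4, and the labels name none. No biological explanation was tested, since the number is not a group of the design, and without these libraries edgeR called 484 transcripts at 18 h, 165 at 24 h and 1080 at 36 h.

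In the 4 camptothecin libraries of 24 h, 21 values were tested for a library far from the others, of which chance picks out about 1 in 20. Gadd45a had a gap of 0.896 of the range (library 1 at 649 CPM, the others at 446 to 467) and Mdm2 0.893 (library 4 at 7.26 CPM, the others at 2.87 to 3.34). Malat1 had 0.898 (library 4 at 3.59%, the others at 1.05% to 1.31%) and the noncoding RNA Meg3 0.935 (library 4 at 0.145%, the others at 0.0335% to 0.0407%).

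The camptothecin effect differed between times for Zbtb16 (adjusted p = 0.0144). For lists, camera tested the difference of effects. Between 24 h and 18 h the regeneration-associated list differed (median difference -0.45, adjusted p = 9.85e-11; adjusted p = 0.187 with an estimated correlation). For 36 h against 18 h it differed by -0.66 (adjusted p = 4.54e-16; 0.0218 as adjusted p with an estimated correlation) and the glucocorticoid-response list by 0.85 (adjusted p = 4.93e-09; 0.0133 as adjusted p with an estimated correlation). The other lists that differed between 36 h and 18 h were fibroblast matrix (0.61, adjusted p = 1.72e-06), pan-neuronal (-0.27, adjusted p = 0.000786), Schwann cell (0.39, adjusted p = 0.000786), erythroid (-1.42, adjusted p = 0.0198), endoplasmic reticulum stress (-0.31, adjusted p = 0.0198) and very long genes (-0.25, adjusted p = 0.0294). With an estimated correlation their adjusted p was 0.156 for the fibroblast and pan-neuronal lists and 0.493 for the rest.

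Other splits of the same samples were fitted for each count. For the average over times 1 of 100 splits, the real one, gave as many as 1913 calls and the highest other gave 912. These were drawn from 14000 relabellings within times, and a random grouping of the libraries is excluded only at that level. They do not test depth or GC trend, which follow the arm. With the log2 library total as a covariate edgeR called 0, and simulated GC trends without a changed transcript gave 419 false calls. Chance cannot be excluded for the difference between times, where 5 of 100 splits gave as many as the 1 real call and the highest other gave 141. For camptothecin against vehicle at 24 h, and for camptothecin at 24 h against 18 h, the real count was 0, which every split must reach (35 of 35 each), so the share says nothing about chance. The highest other split at 24 h, which joined camptothecin library 4 to the vehicle libraries, gave 11 calls. Within camptothecin the highest gave 182, which points to a structure of the samples. With 3 libraries against 3 the 10 splits are too few for a share under 0.05. In each such comparison the real split alone (1 of 10) gave its count, 294 at 18 h, 466 at 36 h, 43 and 268 within vehicle and 95 within camptothecin, and the highest other was 0.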

How the results depend on the processing

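The GC corrections, the covariate, thinning, sums per symbol, limma on the deposited values and the fits without the libraries numbered 4 were chosen only after the data were seen. Counts are given in the order of camptothecin against vehicle at 18 h, 24 h, 36 h and the average, its difference between times, vehicle 24 h and 36 h against 18 h, and camptothecin 24 h and 36 h against 18 h. The main counts by edgeR were 294, 0, 466, 1913, 1, 43, 268, 0 and 95. DESeq2 gave 961, 124, 974, 2580, 12, 360, 571, 1 and 383. limma-voom gave 149, 0, 265, 1810, 0, 21, 166, 0 and 149. limma on the deposited values gave 363, 0, 405, 1963, 1, 111, 392, 0 and 75. Scaling by RLE gave 312, 0, 497, 2020, 1, 66, 294, 0 and 100, and no filter gave 273, 0, 450, 1891, 1, 42, 255, 0 and 94. A fit of the compared groups alone gave 493, 0 and 179 at the 3 times, 95 and 77 within vehicle and 0 and 163 within camptothecin. The GC correction gave 22, 0, 130, 950, 1, 22, 258, 0 and 105, and the library total as a covariate 0, 0, 0, 0, 1, 0, 218, 0 and 64. Thinning gave 462, 0, 558, 1963, 2, 76, 318, 0 and 109, and sums per symbol 500, 0, 625, 1867, 1, 79, 335, 0 and 148. Without the libraries numbered 4 the counts were 484, 165, 1080, 2300, 1, 151, 99, 8 and 210. Fits of fewer samples have fewer degrees of freedom. The covariate lies close to the arm. It also ended the calls of vehicle 24 h against 18 h, where depth separates the groups too (6.08 M to 8.32 M against 3.62 M to 4.38 M). A count of 0 with it cannot tell depth from the comparison itself, and the cause of these shifts was not tested.

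The replicate numbers showed no clear pairing of the samples of the 2 arms. Of 7 pairs with the same number at one time, 1 had a correlation of deviations over 0.1 (-0.21 to 0.23). Across all groups the libraries numbered 4 correlated with each other (0.23 to 0.45). There 9 of 19 libraries correlated best with their own number, which was not set against a random share, so some sharing by number is not excluded. With the replicate number as a block the counts were 435, 0, 845, 2410, 0, 100, 352, 0 and 123, and with the block and the GC correction together 123, 0, 516, 1395, 3, 59, 383, 0 and 135. Lists passing camera at 18 h, 24 h, 36 h and in the average numbered 1, 2, 5 and 2, and with the block 3, 2, 3 and 2. With an estimated correlation they numbered 0, 0, 0 and 0, also with the GC correction; by fry 0, 0, 3 and 2, with the GC correction at the preset value 2, 2, 7 and 2, and without the libraries numbered 4 1, 2, 3 and 2.

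Leaving out 1 library gave counts of 1 to 286 at 18 h, 0 to 1 at 24 h, 1 to 1015 at 36 h, 1427 to 2503 for the average and 0 to 2 for the difference between times. It gave 5 to 76 and 151 to 274 within vehicle, and 0 to 2 and 36 to 84 within camptothecin. The named results had been chosen for passing, so a reversal with 1 library left out was unlikely beforehand. Of them, 922 kept their call and direction over these fits, 424 kept direction without passing and 0 reversed. With the GC correction the numbers were 67, 62 and 0, and with the covariate 17, 110 and 2. Those that reversed, in the average, were Pmaip1 (0.16) and Nr1d2 (0.35), each with adjusted p = 0.997; the cause was not tested. Pseudocounts, array weights and quantile or trend settings were meant for normalised values and were not run. Totals of 3.62 M to 15 M counts limit transcripts near 1 CPM to a few counts per library. Simulated 2-fold changes were recovered in 51% to 62% of transcripts at single times. Those were drawn above a minimum mean count, so the recovery does not cover transcripts near 1 CPM.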

Other observations

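The test of clock genes was chosen only after the result was seen. Some members of the fixed lists moved singly without their list. Averaged over the times and relative to vehicle, the chemokine receptor Ccr2 (-1.40 ± 0.28, SE) and the growth factor receptor Csf1r (-0.96 ± 0.22), both of monocytes and macrophages, fell under camptothecin. The gap junction gene Gja1 fell (-0.79 ± 0.16), and the myelin gene Pmp22 rose (0.49 ± 0.10). The sterol enzyme Msmo1 fell (-0.93 ± 0.17). The clock genes Nr1d1 (0.65 ± 0.16) and Cry2 (0.27 ± 0.06) and the glycolytic enzyme Aldoa (0.52 ± 0.13) rose, and the cyclin Ccna2 fell (-0.68 ± 0.13). All had adjusted p between 0.000711 and 0.00978 and kept their calls when any 1 library was left out. Those fits keep the gap in depth and GC trend between the arms. Of all 44 named transcripts that passed in the average, 24 stayed under 0.05 with the GC correction. With the log2 library total as a covariate 0 of the 44 did, but that total follows the arm.

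A hypothesis was that camptothecin at 18 h resembles a later time after injury. Of the 200 transcripts with the smallest p among rises from 24 h to 36 h in vehicle, 84 were above vehicle under camptothecin at 18 h, with a median log2 fold change of -0.14 and a camera p with an estimated correlation of 0.241. A median at or below 0 had been set beforehand as evidence against the hypothesis. It was not taken as decisive because members went both ways and the median was -0.03 with the GC correction (a camera p of 0.75), a reading fixed after the values were seen, so the hypothesis stays open. At 18 h 5 of 27 regeneration-associated genes rose (the list had a camera adjusted p of 0.362 with an estimated correlation), and the set of later rises as a whole was not higher.

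Of the glucocorticoid-response genes 3 of 9 rose at 36 h, and the list had a camera adjusted p of 0.113 with an estimated correlation. A difference in time-of-day phase between the arms may play a part and stays open. The clock list as a whole had a median of 0.21 and camera adjusted p = 0.216 at 36 h. A test for change in either direction (fry) gave an adjusted p of 0.0455, but 11 of 28 lists were under 0.05 by it, 9 of them with a smaller value, so it was not particular to the clock. In size, 4 of 15 clock genes had a log2 fold change of 0.5 or more. No clock gene passed alone at 36 h. Clock times are not given in the sources used here, and stress or camptothecin itself stays untested as a reason.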
